A study of Mus musculus with 5 samples.

How the data were processed

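Peaks of H2AK119ub1 and H3K27me3 in sciatic nerves of control and Bap1 cKO mice were analysed, with 1 library for each mark and genotype. The labels list 5 samples, of which 4 had a peak list and the input library of the knockout was not used here. Groups were taken from the sample titles. Antibodies and the input are named in the labels, which give no sex and do not say whether the nerves of both marks came from the same pool.

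Reads were processed by the authors. The submitters' processing notes name bcl2fastq 2.20.0.422, Bowtie2, MACS2 and bedtools and the build mm10, without roles or options, and the background used in peak calling is not given in the sources used here. Each deposited list has 9 columns in the order of the MACS2 broad peak format, and peaks were called per library, as the peak names show. The score of the authors is 10 times the −log10 q with decimals dropped, tested on every peak. The deposited fold is a ratio of the peak over the caller's background. The deposited −log10 p and −log10 q are means over a peak, and the lowest −log10 q was close to 1 in every list, which is a q of 0.1. Scores, folds and −log10 values of the authors were used to describe, rank and filter peaks within a list. Values were set side by side across lists in comparisons chosen after seeing the data. These were the common −log10 p limit of 5, the −log10 p at equal fold and the count of peaks of low fold. The highest-scoring peaks at Cdkn2a were also compared. All of these comparisons assume that the caller's scale is the same in each list, which was not tested. Peak names of 3 lists mention a filtered alignment and those of the knockout H2AK119ub1 list do not, so upstream filtering may have differed for that list. Read numbers are not given in the lists, so depth is unknown and a missing peak does not show that a mark was absent.

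Peak coordinates were taken as 1-based, and comparisons used chromosomes 1 to 19, X and Y. Unplaced scaffolds held 5 and 12 H2AK119ub1 peaks and 25 and 46 H3K27me3 peaks, control first, which entered no comparison. Overlap was found with bedtools 2.31.1 and required 1 bp. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks called knockout-only or control-only are those with no overlapping peak of the same mark in the other genotype. In settings that shorten lists by score, number or −log10 p, peaks were compared after shortening, unless all peaks of the other list are named. A single-genotype peak or gene may then still have a weaker peak in the other genotype. Shuffled values are means over 100 draws in which each peak was moved at random within its chromosome, above position 3000000, without regard to unmappable sequence.

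Gene positions came from a RefSeq table of the same build (GRCm38.p6) with 21887 protein-coding genes on these chromosomes and 49943 genes in all. The design fixed before the data were examined called for windows of 2 kb around transcription start sites. The gene table used here gives no strand, so windows of 2 kb around either gene end were used in their place, and a peak at a gene end may lie at the start or the end of transcription. Exons, introns and UTRs are not distinguished for the same reason. A peak between neighbouring genes counts for each, as in Hox clusters. Random lists were not matched on CpG content, since no genome sequence was used here, and Polycomb marks favour CpG-rich promoters.

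The 19 gene lists with 387 entries (378 distinct genes, 9 of them in more than 1 list) were fixed before the data were examined, and all entries were matched to the table. For each list and mark, the percentile is the place of the list's count among 10000 random lists of the same size, ties counted as 0.5, over 38 combinations of list and mark. It describes these libraries and is not a test. Random lists include unmarked genes, so a list rich in marked genes can rank high for single-genotype counts too. Named genes follow a rule fixed at the same time. It takes up to 4 members per list and mark by score, the 10 genes nearest to the highest-scoring knockout-only and control-only peaks at gene ends, the 5 genes with most more and most less cover within 10 kb among genes marked in both, and 10 genes of interest. Members that make up a count of a list, genes with single-genotype peaks of both marks, the Hox clusters and the peaks inside Mpz, Egr2 and Nab2 are named as well, and were chosen after their values were seen. Expected numbers for genes with both marks or both changes are n1 × n2 / N over all protein-coding genes. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only.

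The functions were tested on simulated data before use. With peaks planted at the ends of 200 isolated genes among the 21887, the state of 200 and the location of 200 were recovered, and 2.50% of 200 lists drawn at random fell outside percentiles 2.5 to 97.5. Alternatives fixed before the data were examined were an overlap of at least 0.5 of a peak, the upper 0.5 of each list by score, equal numbers of peaks, stitching within 3 kb (3000 bp), autosomes only, windows of 500 and 5000 bp, at least 1000 bp of a window covered, and all annotated genes. Chosen after seeing the data were whole genes with 2 kb on each side, a common −log10 p of at least 5, and the upper 0.5 of one list against all peaks of the other.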

Results

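The series profiled 2 repressive histone marks by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse sciatic nerve. H2AK119ub1, ubiquitinated histone H2A, is written by Polycomb repressive complex 1 and removed by the deubiquitinase BAP1. H3K27me3, histone H3 trimethylated on lysine 27, is written by Polycomb repressive complex 2. Nerves came from control mice with floxed Bap1 alleles and from conditional knockouts (Bap1 cKO), in which Cre under the Mpz gene, which encodes the main myelin protein of Schwann cells, deletes Bap1. Mice were 4 months old, and 6 nerves entered each condition. Each genotype gave 1 library per mark, and an input library from the knockout was not used here. Whole nerve also holds fibroblasts, endothelial cells, macrophages and perineurial cells, so every peak list covers a mixture of cell types. The authors' peak lists held 35570 H2AK119ub1 peaks in the control and 61217 in the knockout, and 12326 H3K27me3 peaks in the control and 19309 in the knockout. With 1 library per group there is no spread between replicates and no test between genotypes, and the read depth behind the lists is unknown. The values below describe these libraries, intervals cover counting error only, and coordinates are mm10.

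Does loss of Bap1 go with more H2AK119ub1 sites? The knockout list was longer but made of narrower peaks. On the assembled chromosomes, 61205 knockout peaks covered 48.9 Mb with a median width of 548 bp, and 35565 control peaks covered 34.7 Mb with a median width of 609 bp. Of the knockout peaks, 40875 were overlapped by no control peak, and these covered 24.1 Mb. Of the control peaks, 16097 were overlapped by no knockout peak, covering 9.24 Mb. Overlapped control peaks made up 54.7% of their list, against 4.48% on average for control peaks shuffled within their chromosomes. Peaks of at least 5 kb numbered 554 in the control and 266 in the knockout. Every one of the 554 wide control domains held knockout signal, yet knockout peaks covered a median of 65.9% of a domain, and under 50% in 129 of them. In the reverse direction, control peaks touched 262 of the 266 wide knockout domains and covered a median of 85.9%. Above a common −log10 p of 5, the lists held 6255 control and 7941 knockout peaks, which covered 11.6 and 9.13 Mb. With both lists cut at that limit, 5462 knockout and 3982 control peaks had no overlapping peak in the other list. Weaker peaks below the limit may still lie there. Taking an equal number of the highest-scoring peaks from each list gave 20697 and 21130, which equal lengths make nearly equal by construction.

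**Figure D1:**
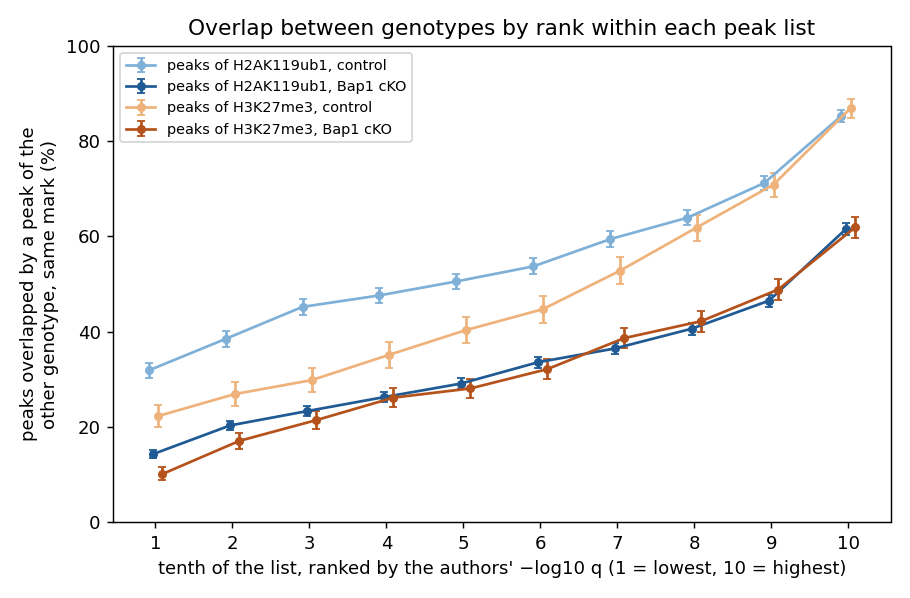
Percentage of peaks in 10 equal parts of each list, ranked by the authors' −log10 q, that were overlapped by at least 1 bp of a peak of the same mark in the other genotype; points are shares with exact 95% binomial intervals. The share climbs with rank in all 4 lists, from 31.9% to 85.3% for control H2AK119ub1 peaks and from 14.3% to 61.6% for knockout H2AK119ub1 peaks.

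Overlap between genotypes rose with the rank of a peak within its own list. In the lowest-ranked 10% of the control H2AK119ub1 list, 31.9% of peaks (exact 95% binomial interval 30.3 to 33.4%) were overlapped by a knockout peak, and in the highest-ranked 10% it was 85.3% (84.1 to 86.4%). The knockout H2AK119ub1 list ran from 14.3% to 61.6%. For H3K27me3, the control list ran from 22.3% to 86.9% and the knockout list from 10.1% to 61.9%. Shares were not matched for width, and wider peaks are met more easily. Median widths of overlapped and other peaks were 845 and 409 bp for control and 899 and 423 bp for knockout H2AK119ub1. Knockout peaks were also set against the shorter control lists, so the ranges of the genotypes are not directly comparable.

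Of 21887 protein-coding genes, 7171 (32.8%) had an H2AK119ub1 peak within 2 kb of either gene end in the knockout and 5445 (24.9%) in the control. In all, 4557 genes had a peak in both, 83.7% of the control genes and above the 1784 that independent lists would share. A further 2614 genes had a peak in the knockout only and 888 in the control only. With equal numbers of peaks the counts were 1577 and 1528, and above a common −log10 p of 5 they were 890 and 866. The highest-scoring knockout-only peaks at gene ends lay beside Cnot6, a subunit of the CCR4-NOT deadenylase (chromosome 11, 49713808 to 49714118, fold enrichment 4.70 as the authors give it, −log10 q 6.75), and Lipo2 (chromosome 19, 33762476 to 33762764, fold 4.98, −log10 q 5.42). Next came peaks beside Ap1m2, Slc29a1, Spata19, Celsr2, Sgms2, Nav2, Tmigd3 and Icosl, of which Sgms2 alone had no control peak at either end. Control-only peaks of highest score lay beside Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123461850 to 123462127), Gm13289, Bahcc1, Elovl3, Crebbp, Gm9780, Gm13287, Ddn, Homer2 and Gper1. Of these genes, Lars2 and Gm9780 alone had no knockout peak at either end. The Lars2 peak combined a −log10 q of 22.1 with a fold of 2.12, below the lower quartile of 2.78 of that list.

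Among genes with H2AK119ub1 in both genotypes, the largest differences in cover went both ways. Within 10 kb of the gene ends, peaks over the LIM homeobox gene Lhx2 covered 25198 bp in the control and 12707 bp in the knockout. For the homeobox gene Pitx2 the values were 24677 and 13138 bp, for the ephrin gene Efnb1 19063 and 8472 bp, for Hoxd3 20487 and 9972 bp, and for Hoxc13 22840 and 12533 bp. On the side of more cover stood Tex33, with 4577 bp in the control and 18868 bp in the knockout. Tgm2, which encodes transglutaminase 2, had 3975 and 15784 bp, A530016L24Rik 1741 and 12174 bp, Padi4 229 and 10360 bp, and Fam166c 1464 and 11189 bp.

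Bap1 itself had no peak of either mark within 2 kb of its ends in any list, and peak lists do not show whether it was deleted. Sox10, the Schwann cell lineage transcription factor, had none either. Cdkn2a, a cell cycle inhibitor and classic Polycomb target (chromosome 4, 89274473 to 89294619), had both marks in both genotypes. H2AK119ub1 peaks within 10 kb of the ends of Cdkn2a covered 14727 bp in the control and 6647 bp in the knockout, and H3K27me3 peaks 13343 and 13723 bp. The H3K27me3 order was the other way in the windows of 2 kb (5643 and 5129 bp). The highest-scoring H2AK119ub1 peak at Cdkn2a was 670 bp wide in the knockout (fold 5.19, −log10 q 8.14) and 6047 bp wide in the control (fold 3.83, −log10 q 4.94). The knockout peak lay inside the control peak. The −log10 q is a mean over a peak, so peaks of such unlike width do not show a stronger mark in either genotype. Genes of the nerve injury response, namely Shh, Gdnf, Olig1 and Sox2, carried both marks in both genotypes. H2AK119ub1 cover within 10 kb was 4593 and 4007 bp at Shh, 8177 and 6095 bp at Gdnf, 7377 and 3701 bp at Olig1, and 6065 and 2732 bp at Sox2, control first. In the windows of 2 kb the order was the other way at Shh (905 and 1193 bp) and Gdnf (2572 and 2806 bp). At Jun, which drives the repair program of Schwann cells, the control list held an H2AK119ub1 peak (chromosome 4, 95050922 to 95052010, fold 2.09) and the knockout list none. The Jun fold was among the lowest of the control list, where a fold of 2.18 stood at percentile 0.6185.

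**Figure D2:**
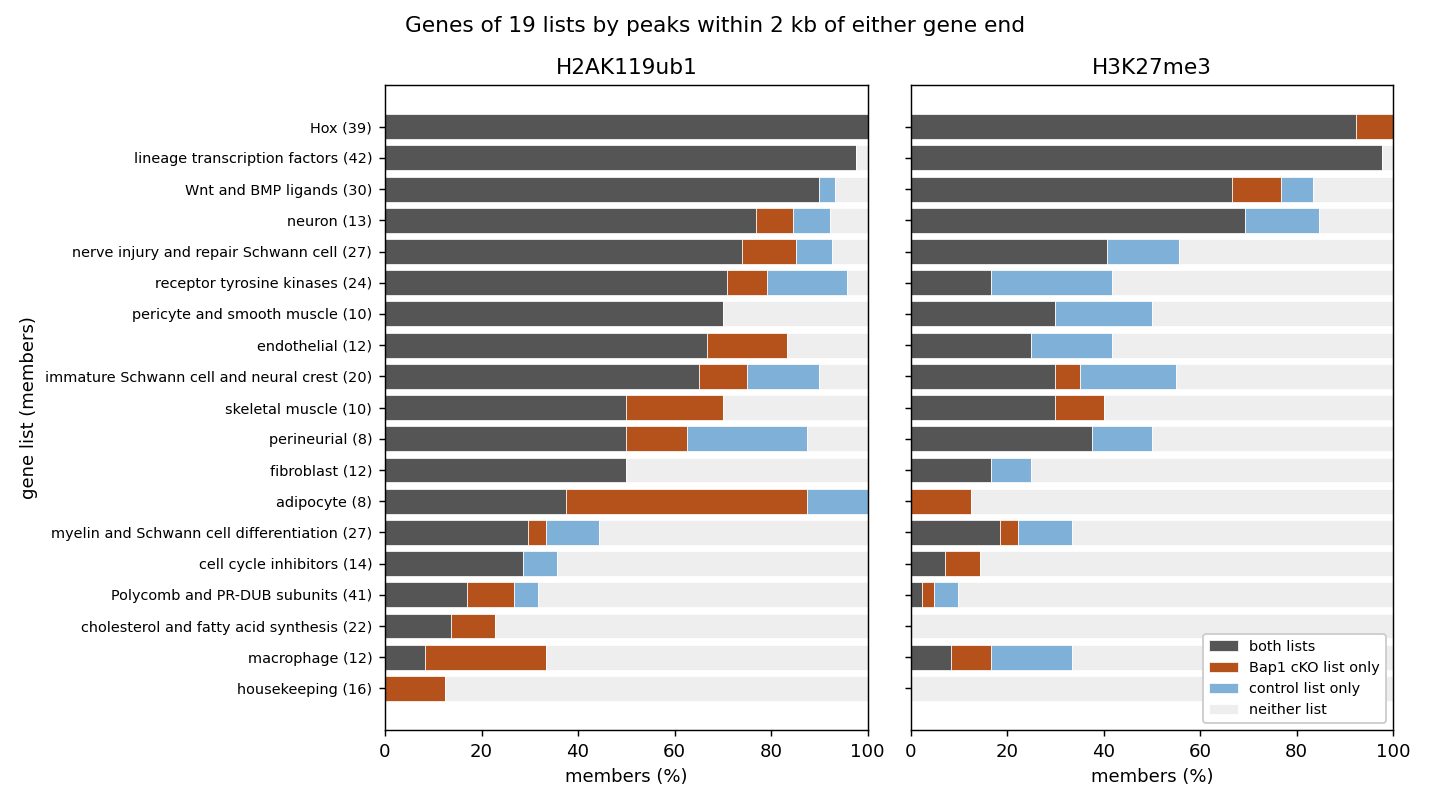
Members (%) of 19 gene lists with a peak within 2 kb of either gene end in both lists, in the Bap1 cKO list only, in the control list only or in neither, for H2AK119ub1 (left) and H3K27me3 (right); the number of members stands in brackets. All 39 Hox genes carry H2AK119ub1 in both genotypes, and no housekeeping gene carries H3K27me3 in either.

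Developmental gene lists were H2AK119ub1-marked in both genotypes almost throughout. All 39 Hox genes had a peak in both, as did 41 of 42 lineage transcription factors (Tlx3, Dlx2, Lhx1 and Nkx6-1 with the highest scores) and 27 of 30 Wnt and BMP ligands, with Wnt5a in the control only. Random lists of the same size held 8.11, 8.76 and 6.25 such genes on average, and all 3 lists stood at percentile 100 of 10000 random lists. Of 27 nerve injury and repair genes, 20 had a peak in both, Runx2, Igfbp5 and Ucn2 in the knockout only, and Jun and Megf10 in the control only. Immature Schwann cell and neural crest genes, 20 in number, had 13 in both, Erbb3 and Ednrb in the knockout only, and Jun, L1cam and Snai2 in the control only. Of 24 receptor tyrosine kinases, 17 were in both and Erbb3 and Insr in the knockout only. Erbb2, Fgfr1, Kit and Ror1 were in the control only, a control-only count at percentile 99.2. Of kinases with a control peak, 4 of 21 were control-only, against 888 of 5445 genes in all. The percentile therefore does not show that kinases lost peaks more often than other marked genes. Of 27 myelin and Schwann cell differentiation genes, 8 had a peak in both, Mpz in the knockout only, and Mag, Nab2 and Fa2h in the control only. The knockout list did hold a peak inside Nab2 (chromosome 10, 127662970 to 127663174, fold 2.64), outside the windows at its ends. The Mpz peak (chromosome 1, 171158335 to 171160451, inside the gene near its high-coordinate end) had a fold of 1.91, at percentile 0.0376 of its list, and a −log10 q of 1.97.

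Lists of other cell types and functions varied widely. Among 8 adipocyte genes, Adipoq, Fabp4, Lep and Cfd had a peak in the knockout only, a count at percentile 99.4 of random lists, while 3 had a peak in both and Pparg in the control only. The strongest of these, at Cfd, had a −log10 q of 2.04. The knockout-only count of this list was 1 with equal numbers of peaks or windows of 500 bp and 2 with windows of 5 kb. Of adipocyte genes with a knockout peak, 4 of 7 were knockout-only, against 2614 of 7171 genes in all. Macrophage genes (12) had 1 in both and Spi1, Itgam and Cd163 in the knockout only. Endothelial genes (12) had 8 in both and Pecam1 and Tie1 in the knockout only, and skeletal muscle genes (10) had 5 in both and Ckm and Mylpf in the knockout only. Perineurial genes (8) had 4 in both, Cldn1 in the knockout only and Itga4 and Lypd2 in the control only, and neuron genes (13) had 10 in both, Snap25 in the knockout only and Syp in the control only. Fibroblast genes (12) and pericyte and smooth muscle genes (10) had 6 and 7 in both and none in a single genotype. Of 41 Polycomb and PR-DUB subunits, 7 had a peak in both, Pcgf2, Kdm2b, Aebp2 and Usp16 in the knockout only, and Ogt and Bmi1 in the control only. Cell cycle inhibitors (14) had 4 in both and Btg2 in the control only. Within 10 kb of the ends of Btg2, cover was 285 bp in the control and 3957 bp in the knockout. Windows of 5 kb gave this list 4 knockout-only members and 1 control-only. Cholesterol and fatty acid synthesis genes (22) had 3 in both and Elovl6 and Mvd in the knockout only. Of 16 housekeeping genes, none had a peak in both, and Gapdh and Polr2a had one in the knockout only. More knockout-only than control-only members were found in 8 of the 19 lists and the reverse in 6, but with equal numbers of peaks in 4 and 11. The order within a list turned in at least 1 of 4 alternative settings for 6 lists, among them the injury, myelin and Polycomb lists.

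**Figure D3:**
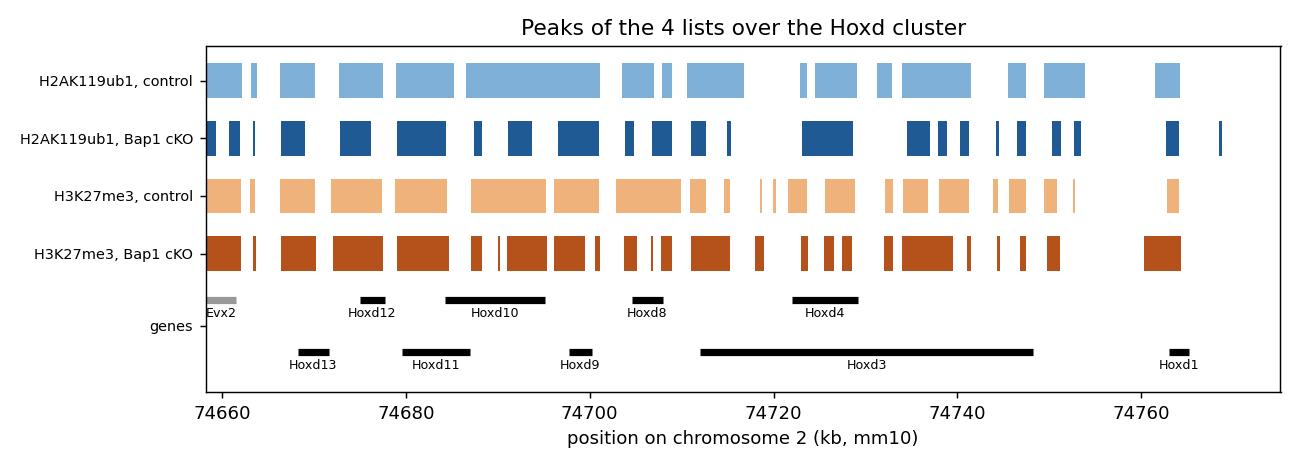
Peaks of the 4 lists (coloured bars) and protein-coding genes (black and grey bars) over the Hoxd cluster and 10 kb on each side, chromosome 2, in kb of mm10. Control H2AK119ub1 peaks cover 64.1% of the cluster and knockout peaks 38.8%, in 14 and 19 pieces.

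Hox clusters kept both marks in both genotypes, with less H2AK119ub1 cover in the knockout at each of the 4 clusters. This count over whole clusters was chosen after the peaks had been seen. From the first to the last Hoxd gene (chromosome 2, 74668225 to 74765142), 14 control peaks covered 64.1% and 19 knockout peaks 38.8% of the span. Cover was 61.3% and 46.4% at Hoxa, 50.6% and 43.6% at Hoxb without the distant Hoxb13, and 46.1% and 35.4% at Hoxc. The widest H2AK119ub1 peak at Hoxb measured 14395 bp in the control and 4548 bp in the knockout. H3K27me3 cover was 55.5% and 49.0% at Hoxd, 47.9% and 37.9% at Hoxa and 38.8% and 36.1% at Hoxc, but 39.4% and 46.0% at Hoxb.

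Does H3K27me3 follow H2AK119ub1? The knockout H3K27me3 list was also longer and made of narrower peaks, but covered about as much sequence. On the assembled chromosomes, 19263 knockout peaks covered 14.5 Mb with a median width of 414 bp, and 12301 control peaks covered 14.0 Mb with a median width of 636 bp. Knockout-only peaks numbered 12970 (6.06 Mb) and control-only peaks 6499 (3.90 Mb). Overlapped control peaks made up 47.2% of their list, against 1.46% after shuffling. Peaks of at least 5 kb numbered 359 in the control and 192 in the knockout, and all of these domains were touched by the other list, with median cover of 75.6% and 97.7%. Above a common −log10 p of 5 the order of the single-genotype counts turned, to 2799 knockout-only and 2850 control-only. Equal numbers of peaks gave 7236 and 7556, which equal lengths make nearly equal by construction.

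At gene ends the H3K27me3 counts were close, with 2875 genes in the control, 2759 in the knockout and 2043 in both, against 362 for independent lists. Peaks were found in the knockout only at 716 genes and in the control only at 832. This order turned with windows of 5 kb, to 1250 and 1028, and over whole genes with 2 kb on each side, to 1414 and 861, and it also turned over all annotated genes. Control-only genes led by more with equal numbers of peaks (372 and 1177), above a −log10 p of 5 (231 and 845) and with at least 1 kb of window covered (214 and 646). Knockout-only peaks of highest score lay beside Gm52259 (chromosome 16, 65910411 to 65910756, fold 5.45, −log10 q 8.77), Rps6ka2, a ribosomal S6 kinase (chromosome 17, 7089489 to 7089838, fold 5.52, −log10 q 8.28), Tuba8, Eif4ebp2, Gnl1, Zpbp2, Gm9758, C1ql4, Cdc20b and Clca3b. Control-only peaks of highest score lay beside Slc4a8, Atp6v1b1, Shisa3, Epha3, Eya1, Shisa8, H2-T-ps, Gm13288, Mien1 and Prtg. Of these genes, Slc4a8, Atp6v1b1, Shisa8, Gm13288 and Mien1 also had a knockout peak at an end. Tuba8, C1ql4 and Cdc20b likewise had a control peak at an end. Among genes marked in both, cover within 10 kb was higher in the knockout at Hoxb4 (1485 bp in the control and 7907 bp in the knockout), Hoxb2 (1587 and 6663 bp), H2-Q2 (2244 and 6180 bp), Gip (2000 and 5840 bp) and Hoxb5 (11580 and 15370 bp). It was lower at Lhx2 (25831 and 13041 bp), at Cyp26b1, which degrades retinoic acid (15046 and 3268 bp), and at Cdh22 (21998 and 10764 bp), Gata2 (15619 and 6399 bp) and Mthfsd (15856 and 7369 bp).

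Control-only members prevailed in 11 of the 19 lists for H3K27me3 and knockout-only members in 5. Of 24 receptor tyrosine kinases, Egfr, Erbb4, Fgfr2, Fgfr3, Kit and Ror2 had a peak in the control only (percentile 100), 4 in both and none in the knockout only. At Fgfr3 the control peak (chromosome 5, 33721576 to 33723670) had a fold of 3.91. Among injury and repair genes, 11 of 27 had a peak in both and Gfap, Ngfr, Megf10 and Cxcl14 in the control only (percentile 99.0). Among immature Schwann cell and neural crest genes, 6 of 20 were in both and Ednrb in the knockout only. Ngfr, Ncam1, Sox9 and Ets1 were in the control only (percentile 99.6). Of genes with a control peak, 832 of 2875 were control-only in all. The counts were 6 of 10 for kinases, 4 of 15 for injury genes and 4 of 10 for immature Schwann cell genes. Myelin genes (27) had 5 in both, Gjb1 in the knockout only, and Mbp, Egr2 and Fa2h in the control only. The knockout list did hold a peak inside Egr2, a master regulator of myelination, from 67538889 to 67539832 on chromosome 10, outside the windows at its ends. Control-only members outnumbered knockout-only members in all 4 alternative settings for the kinase, injury and immature Schwann cell lists. The same held for the neuron, endothelial and perineurial lists. Control-only genes also led over all genes in the upper 0.5 of each list (690 against 484), with equal numbers of peaks (1177 against 372) and with windows of 500 bp (775 against 414). Knockout-only genes led with windows of 5 kb (1250 against 1028). In the former settings the order is thus not particular to these lists. The kinase counts narrowed to 2 against 1 in the upper 0.5 of each list and 3 against 1 with windows of 5 kb.

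Hox genes carried H3K27me3 in both genotypes at 36 of 39 genes, and Hoxb3, Hoxc4 and Hoxc6 in the knockout only. Lineage transcription factors were marked in both at 41 of 42 genes. Wnt and BMP ligands (30) had 20 in both, Wnt6, Wnt11 and Bmp5 in the knockout only, and Wnt5b and Bmp7 in the control only. The remaining lists were small: neuron genes (13) had 9 in both and Elavl4 and Slc17a6 in the control only, endothelial genes (12) 3 in both and Tek and Cldn5 in the control only, and macrophage genes (12) 1 in both, Cd163 in the knockout only and Cx3cr1 and Mrc1 in the control only. Pericyte and smooth muscle genes (10) had 3 in both and Myh11 and Notch3 in the control only, perineurial genes (8) 3 in both and Tjp1 in the control only, fibroblast genes (12) 2 in both and Sox9 in the control only, and skeletal muscle genes (10) 3 in both and Tnnt3 in the knockout only. Adipocyte genes (8) had Lep in the knockout only. Cell cycle inhibitors (14) had 1 in both and Cdkn2b in the knockout only, and Polycomb and PR-DUB subunits (41) had 1 in both, Cbx2 in the knockout only and Cbx4 and Phc2 in the control only. None of the 22 cholesterol and fatty acid synthesis genes and none of the 16 housekeeping genes had an H3K27me3 peak in either genotype. The order of knockout-only and control-only members turned in at least 1 setting for the Hox, Wnt and BMP, and cell cycle lists.

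The marks coincided in both genotypes. In the control, 2380 genes had peaks of both marks at their ends, 3.33 times the 715 of independent lists, and in the knockout 2209, 2.44 times the 904 of independent lists. Of the H3K27me3 genes, 82.8% in the control and 80.1% in the knockout had H2AK119ub1 as well, while of the H2AK119ub1 genes 43.7% and 30.8% had H3K27me3. In base pairs, the marks shared 7.99 Mb in the control and 5.62 Mb in the knockout, against 0.215 and 0.301 Mb after shuffling. At the level of peaks, 48.6% of control H3K27me3 peaks (5977 of 12301) and 34.2% of knockout H3K27me3 peaks (6587 of 19263) overlapped an H2AK119ub1 peak.

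Genes with a knockout-only peak of both marks numbered 131, against 85.5 for independent lists. Ednrb, the endothelin B receptor gene, Cd163, a macrophage scavenger receptor gene, and Lep, which encodes leptin, were among them. A further 110 genes had H2AK119ub1 in the knockout only and H3K27me3 in the control only, against 99.4. Control-only peaks of both marks were found at 74 genes, against 33.8, among them Megf10, Fa2h and Kit. H2AK119ub1 in the control only with H3K27me3 in the knockout only was found at 57 genes, against 29.0. These counts over all genes do not tie the changes of the marks together, since the 4557 genes with H2AK119ub1 in both genotypes also had H3K27me3 in the control only at 489 genes and in the knockout only at 254. The order of 131 over 74 turned in the upper 0.5 of each list by score (80 and 96), with equal numbers of peaks (44 and 227) and with windows of 500 bp (69 and 121).

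Peaks of all lists lay at gene ends more often than shuffled peaks. Of H2AK119ub1 peaks, 18.3% in the control and 15.3% in the knockout overlapped a window of 2 kb around a gene end, against 7.38% and 7.13% after shuffling, and 38.2% and 36.9% lay elsewhere in gene bodies. Of H3K27me3 peaks, 26.0% in the control and 17.2% in the knockout were at gene ends, against 7.57% and 6.97%, and 26.6% and 26.1% in gene bodies. By covered length, gene ends took 29.9% and 21.9% for H2AK119ub1 and 45.8% and 31.8% for H3K27me3, control first. Peaks found in both genotypes were at gene ends in 23.7% of cases for control H2AK119ub1 and 33.8% for control H3K27me3. Knockout-only peaks were at gene ends in 10.97% for H2AK119ub1 and 9.22% for H3K27me3, and control-only peaks in 11.8% and 19.02%. Chromosome X held 3.02% of H2AK119ub1 peaks in the control and 1.43% in the knockout, and 2.68% and 4.11% of H3K27me3 peaks.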

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

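The tests of explanations in this part were chosen after the results had been seen, except the comparison with other myelin genes, and so were the −log10 p limit of 5 and the setting of whole genes with 2 kb on each side. None of the differences between genotypes or between marks named here was tested, since each group has 1 library.

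The share of peaks on chromosome X went in opposite directions for the marks: it was 3.02% of H2AK119ub1 peaks in the control (exact 95% binomial interval 2.84 to 3.20%) and 1.43% in the knockout (1.33 to 1.52%). It was 2.68% of H3K27me3 peaks in the control (2.40 to 2.98%) and 4.11% in the knockout (3.84 to 4.40%). A knockout pool with fewer X chromosomes would lower the share for both marks, and the 4.11% for H3K27me3 argues against this as the whole cause. Pools of different sex for each antibody could not be examined for H2AK119ub1, since neither of its lists held a peak on Y. The H3K27me3 lists held 6 peaks on Y in the control (0.0487%) and 38 in the knockout (0.197%). The shares on X and Y thus rose together for H3K27me3. The labels give no sex, and 1 library per group does not settle the question. An effect of the genotype on X-linked chromatin stays open and untested.

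The longer H2AK119ub1 list of the knockout is a pattern that sequencing or filtering might produce. Higher effective depth would give a higher −log10 p at the same fold, but at folds of 2.9 to 3.1 and widths of up to 400 bp, the median −log10 p was 3.92 in the control and 3.78 in the knockout, a difference of −0.140. The knockout list reaches down to a lower −log10 p, and the difference was −0.10 above a common 3.5 but 0.025 above 4, so depth stays open. Reads from multi-copy sequence, kept for want of a filter, would add peaks of low fold and high significance if the background held such reads too. Peaks with a fold under 2 and a −log10 q of at least 3 numbered 9 in the knockout and 26 in the control. The background is not known, so these counts cannot decide whether the missing filter matters. Calls spread evenly along a chromosome would lie at gene ends as often as shuffled peaks. The share was 10.97% for knockout-only peaks, above the highest of 100 shuffles at 7.11%, and 11.8% for control-only peaks. Shuffling ignored unmappable sequence, so this argues only against even placement of all knockout-only peaks. Some random calls among the knockout-only peaks are not excluded. An effect of Bap1 loss and a chance difference between single libraries both stay open.

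Peaks of both marks over Mpz were listed in the knockout only, on chromosome 1 at 171158335 to 171160451 for H2AK119ub1 and at 171156053 to 171156266 and 171158301 to 171159042 for H3K27me3, all inside the gene. Their folds of 1.91, 2.58 and 2.44 were among the lowest of their lists, at percentiles of 0.373 and below. Low folds in called peaks might come from a raised local background, as extra copies of Mpz sequence carried by the Cre transgene would give, but this was proposed after the folds were seen, so the percentile of 0.373 is no independent evidence for it. High background over strongly transcribed myelin genes would lower folds at other such genes of the list as well. The 44 knockout peaks over 12 other myelin genes had a median percentile of 36.3, and none was as low as those at Mpz. Transcription was not measured here and these genes include regulators such as Egr2, so this comparison cannot decide the point. Which Mpz sequence the transgene holds is not given in the labels, so a true mark at Mpz stays open.

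Genes with a peak at an end in a single genotype were more often knockout-only for H2AK119ub1 (2614 against 888 control-only) and more often control-only for H3K27me3 (716 knockout-only against 832). The H2AK119ub1 counts came close with equal numbers of peaks (1577 and 1528) and above a −log10 p of 5 (890 and 866), and the H3K27me3 order turned in 3 alternative settings. Unplaced scaffolds, which entered no comparison, held 12 H2AK119ub1 peaks in the knockout and 5 in the control, and 46 and 25 H3K27me3 peaks.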

How the results depend on the processing

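Whole genes with 2 kb on each side, a −log10 p of at least 5 and the upper part of one list against all peaks of the other were chosen after the data had been seen. Of 100 values under alternative settings, 47 stayed within 1.5 times the count or inside the binomial interval and 42 moved further. The other 11 were knockout-only counts that turned in order against their control-only counts. These control-only counts were judged by size alone, and some of them are among the 47. Overlap of at least 0.5 of a peak, stitching and autosomes alone left the single-genotype peak counts in the same order and within that range. Except for equal and upper lists, whose lengths are fixed by construction, the cause was not tested. Pairs below give knockout-only before control-only.

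Equal numbers of peaks turned the order of single-genotype peaks (H2AK119ub1 20697 and 21130, from 40875 and 16097, and H3K27me3 7236 and 7556, from 12970 and 6499). Equal lengths make these peak counts nearly equal by construction. The H2AK119ub1 genes moved to 1577 and 1528, from 2614 and 888, and the H3K27me3 genes to 372 and 1177, from 716 and 832. Genes with single-genotype peaks of both marks turned to 44 and 227, from 131 and 74. Gene lists with more knockout-only members turned to 4 for H2AK119ub1, from 8, with 11 more control-only, from 6, and fell to 2 for H3K27me3, from 5.

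The upper 0.5 of each list by score held 21278 and 9027 H2AK119ub1 and 6338 and 3131 H3K27me3 single-genotype peaks. Genes with both marks were then 1536 in the control, from 2380, and 1324 in the knockout, from 2209. Genes with single-genotype peaks of both marks turned to 80 and 96. Shares of peaks at gene ends were 23.8% and 19.02% for H2AK119ub1 and 32.6% and 20.04% for H3K27me3, control first, from 18.3%, 15.3%, 26.0% and 17.2%. Against all peaks of the other list, the upper 0.5 held 17210 and 5917 H2AK119ub1 and 5320 and 2248 H3K27me3 peaks.

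With a −log10 p of at least 5 in both lists, single-genotype peaks were 5462 and 3982 for H2AK119ub1 and, in turned order, 2799 and 2850 for H3K27me3. Genes were 890 and 866 for H2AK119ub1 and 231 and 845 for H3K27me3.

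Windows of 500 bp gave 1576 and 899 H2AK119ub1 genes, 414 and 775 H3K27me3 genes, 1376 knockout genes with both marks, and 69 and 121 genes with single-genotype peaks of both marks, a turned order. Lists with more knockout-only members were then 4 for H2AK119ub1, a turned order against 9, and 0 for H3K27me3. Windows of 5 kb turned the H3K27me3 genes to 1250 and 1028, and gave 254 and 76 genes for both marks. Lists with more control-only members were 3 for H2AK119ub1, and those with more knockout-only members 3 for H3K27me3. Shares at gene ends were 27.2% and 24.6% for H2AK119ub1 and 35.9% and 26.6% for H3K27me3, control first.

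At least 1 kb of covered window gave 1193 and 722 H2AK119ub1 genes and 214 and 646 H3K27me3 genes. All annotated genes gave 5778 and 1904 for H2AK119ub1 and, in turned order, 1693 and 1513 for H3K27me3. Whole genes turned H3K27me3 to 1414 and 861. Read depth is unknown, so a gene without a peak in a list may still carry the mark below the calling limit, and the 890 and 866 H2AK119ub1 genes at a common −log10 p share that limit.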

Other observations

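The following counts were made after the peaks had been seen. Genes marked in both genotypes by H2AK119ub1 differed in how H3K27me3 was distributed. Of the 4557 such genes, 1711 had H3K27me3 in both genotypes, 489 in the control only, 254 in the knockout only and 2103 in neither. Among the 2614 genes with H2AK119ub1 in the knockout only, 2260 had no H3K27me3 peak in either genotype, as did 18296 of all 21887 genes. On chromosome X, 52 of 966 protein-coding genes had H2AK119ub1 in the knockout only and 66 in the control only, the reverse of the order over all genes. For H3K27me3 the counts on X were 34 and 36, so the higher share of knockout peaks on X was not matched by more knockout-only genes there.

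The widest peak of all 4 lists was the same stretch of chromosome 8, about 87 kb long, from 123537390 to 123624478 in the control H2AK119ub1 list, and overlapped no protein-coding gene. Its edges were nearly the same for both marks and genotypes, and its fold was 13.7 in the control H3K27me3 list. Whether it holds multi-copy sequence was not examined, so it is not shown to be a domain of either mark.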
